A study of Homo sapiens with 6 samples.

How the data were processed

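RNA was measured by RNA sequencing in 6 samples of NCI-H1688, labelled as a small cell lung cancer (SCLC) cell line, established from a liver metastasis. Per the labels' protocols, every sample was kept for 48 h in medium with 0.1 ug/ml doxycycline, a tetracycline analogue that here switches on a short hairpin RNA (shRNA), which lowers the messenger RNA it matches. There were 3 samples labelled shControl and 3 labelled shFOXM1. Groups and replicate numbers were taken from the labels. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The hairpin sequences are not given in the sources used here.

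Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with the NEBNext Ultra RNA kit for Illumina. CASAVA 1.8, HISAT2, featureCounts 1.5.0-p3 and the human genome build GRCh38 are named in the submitters' processing notes. The HISAT2 version, the strand setting of the counting and the rule for reads that overlap several genes are not given in the sources used here. The authors deposited FPKM, fragments divided by gene length and by library size, for 58735 genes, with gene lengths, coordinates and biotypes. FPKM compares 1 gene between samples but depends on the library size the authors chose. All 58735 gene identifiers, with their start and end positions, were matched to GENCODE release 29 on GRCh38, and coordinates below are from that build.

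FPKM multiplied by gene length was a whole multiple of a single step in each sample for 100% of values above 0, within a tolerance of 0.01 of a read. The reads behind each value were therefore recovered, and their totals lay between 15957459 and 19699833 per sample. The denominators implied by the steps were 93.2%, 96.3% and 93.9% of these totals in shControl replicates 1, 2 and 3. They were 91.4%, 91.9% and 92.8% in shFOXM1 replicates 1, 2 and 3, below every shControl sample. The deposited scale therefore raises the shFOXM1 values relative to scaling by total recovered reads. How the authors computed the denominators is not given in the sources used here. Low genes carry large counting error, and floors given for genes without reads, 3 reads in the sample where a read is worth most, cover counting error only.

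Genes with a mean FPKM of at least 1 over the 6 samples were tested, 11728 in all. log2(FPKM + 0.5) was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend, 1 coefficient for the group and no other term. P-values are two-sided, from limma's moderated test, adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes. A direction word such as rose or fell is used only of genes or lists that passed the test.

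Before the data were examined, 29 gene lists were fixed, from textbook knowledge. They were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 25 lists tested, after members under the filter and lists with fewer than 3 tested members had been left out. Each list's median log2 fold change is given. The same test with an estimated correlation and limma's fry were run beside it. FOXM1 itself was left out of the mitosis list. Counts of members passing the test are over all genes tested, and counts adjusted over the list alone stand beside them. Of the 29 lists, 6 were set as primary. The immediate early and heat shock lists were fixed as signs of handling of the samples.

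Genes were named by a rule fixed at the same time. It takes FOXM1, 5 SCLC subtype factors, the 6 protein-coding genes with the largest rise and the 6 with the largest fall among genes called with groups that do not overlap, and, from each list, the 2 called members with the largest absolute log2 fold change, or 4 for a primary list. Not every gene that the rule selects is printed. Members named where a count was 5 or fewer were chosen after their values were seen. So were the matrix genes of the closing section that were barely detected in shControl samples. The collagen and signalling tests of that section were written before they were run, for patterns picked from these data. Some genes of those tests had been seen in other lists.

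The recovery of reads, the fit and the list test were tested on simulated data with the real gene lengths and library sizes and a spread estimated from these samples. In 3 runs of 11728 genes with 200 changed, the recovered reads were exact for 100% of values, 95.7% of 2-fold and 78% of 1.5-fold changes were called, and a mean of 10.3 calls, or 5.62% of calls, was false. None of 75 lists of unchanged genes was called; simulated genes varied independently, which real genes need not do.

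The alternatives were another pseudocount (0.1 or 1), another filter (none, or a mean FPKM of at least 0.1 or 5), protein-coding genes only, rescaling to TPM, scaling by median ratios, quantile normalization, a replicate block, leaving out each sample in turn, other variance models and weights, voom on the recovered reads, and, for lists, camera with an estimated correlation and fry. A range over all alternatives includes fry, which tests against no change; one over the camera alternatives does not. Scaling to the total of recovered reads, with or without mitochondrial genes, was added after the data had been seen. No sample was left out.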

Results

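The data comprised gene-level RNA sequencing values from NCI-H1688 cells in which doxycycline had induced either a control hairpin or a hairpin against FOXM1, a forkhead transcription factor known for driving genes of the G2 phase and mitosis. The comparison asks which genes differ between these hairpins in this line, which the labels call SCLC and whose identity was not tested here. No samples without doxycycline were measured. Other effects of the hairpin, or differences between the cultures of the 2 groups, cannot be told apart from loss of FOXM1 in any result below. There were 3 samples per group, with 15957459 to 19699833 recovered reads per sample, and 21902 to 23021 genes had a value above 0.

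FOXM1 (ENSG00000111206, chromosome 12, 2857681 to 2877155, minus strand, GRCh38) fell in the shFOXM1 samples. Its level was 11.6, 10.4 and 10.3 FPKM in the shControl samples and 4.50, 5.89 and 6.004 FPKM in the shFOXM1 samples, resting on 755 to 891 and 360 to 538 reads. The means were 10.8 ± 0.743 FPKM (SD, n = 3) and 5.46 ± 0.840 FPKM (SD, n = 3). The log2 fold change was -0.93 (SE 0.11, limma adjusted p = 0.00110), a 1.90-fold lower level, and FOXM1 transcripts remained detectable in all 3 shFOXM1 samples.

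**Figure D1:**
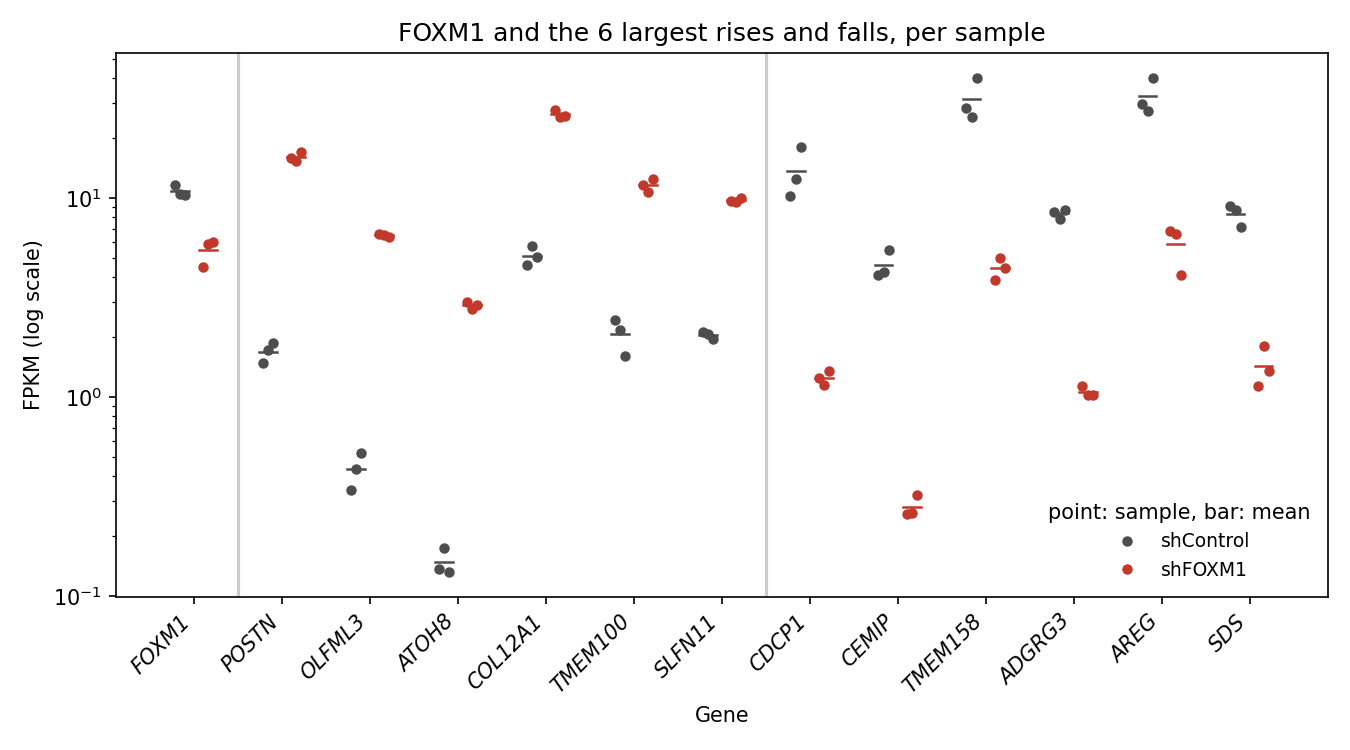
FPKM on a log axis of FOXM1, of the 6 protein-coding genes with the largest rise and of the 6 with the largest fall, in each of the 3 shControl (grey) and 3 shFOXM1 (red) samples; points are samples and bars are means. FOXM1 lay between 4.50 and 6.004 FPKM in shFOXM1 samples and between 10.3 and 11.6 FPKM in shControl samples.

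Among protein-coding genes whose groups did not overlap, the largest rises were in POSTN, OLFML3, ATOH8, COL12A1, TMEM100 and SLFN11. POSTN (chromosome 13, 37562583 to 37598844), which encodes the matrix protein periostin, rose from 1.69 ± 0.200 to 16.0 ± 0.876 FPKM (SD, n = 3 each), a log2 fold change of 2.92 (SE 0.08, adjusted p = 5.70e-06). OLFML3, a secreted glycoprotein (chromosome 1, 113979391 to 114035572), rose by 2.91 on the log2 scale, from 0.432 to 6.48 FPKM. The basic helix-loop-helix factor ATOH8 (chromosome 2, 85751344 to 85788066) rose by 2.38, from 0.147 to 2.88 FPKM. COL12A1, which encodes a fibril-associated collagen (chromosome 6, 75084326 to 75206051), rose by 2.26, from 5.12 to 26.3 FPKM, and the transmembrane protein gene TMEM100 (chromosome 17, 55719627 to 55732121) by 2.24, from 2.07 to 11.6 FPKM. SLFN11, whose product blocks stressed replication forks (chromosome 17, 35350305 to 35373701), rose from 2.04 ± 0.0891 to 9.70 ± 0.242 FPKM, a log2 fold change of 2.01 (SE 0.06, adjusted p = 5.70e-06). The order depends on the pseudocount: at 0.1 the log2 fold changes were 3.64 for OLFML3, 3.59 for ATOH8 and 3.18 for POSTN.

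The largest falls by the same rule were in CDCP1, CEMIP, TMEM158, ADGRG3, AREG and SDS. CDCP1, a transmembrane substrate of Src family kinases (chromosome 3, 45082278 to 45146422), fell from 13.6 ± 4.04 to 1.25 ± 0.0954 FPKM, a log2 fold change of -2.97 (SE 0.18, adjusted p = 7.78e-05). CEMIP, a hyaluronan-degrading protein gene (chromosome 15, 80779343 to 80951776), fell by 2.70 on the log2 scale, from 4.60 to 0.281 FPKM. TMEM158 (chromosome 3, 45224466 to 45226278) fell by 2.67, from 31.3 to 4.43 FPKM, and the adhesion receptor gene ADGRG3 (chromosome 16, 57668187 to 57689378) by 2.50, from 8.35 to 1.06 FPKM. AREG, which encodes the EGFR ligand amphiregulin (chromosome 4, 74445134 to 74455009), fell by 2.39, from 32.3 ± 6.55 to 5.83 ± 1.49 FPKM, and SDS, serine dehydratase (chromosome 12, 113392445 to 113426301), by 2.20, from 8.32 to 1.43 FPKM. At a pseudocount of 0.1 the log2 fold change was -3.62 for CEMIP and -3.30 for CDCP1.

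Of 11728 tested genes, 1498 were called higher and 1701 lower in shFOXM1 samples, 27.3% in all, and 95.0% of the called genes changed by less than 2-fold. At least 2-fold changes were called for 61 genes that rose and 100 that fell. The groups did not overlap for 46.6% of tested genes, where chance gives 10%. The first principal component held 54.0% of the variance and separated the groups. Pearson correlations of log2 values across genes were 0.986 to 0.990 within groups and 0.971 to 0.978 between them, and no pair of samples agreed within sampling noise. The counts of higher genes were 953, 934 and 925 without shFOXM1 replicate 1, 2 or 3, and those of lower genes 1115 and 1017 without shFOXM1 replicate 2 or 3. Lower genes were 53.2% of calls as deposited, 68.8% after rescaling to TPM (1115 higher, 2457 lower) and 65.0% after scaling to total recovered reads (1234 higher, 2290 lower). After quantile normalization they were 48.0% (1727 higher, 1592 lower). The median log2 change of all tested genes was -0.0102 as deposited and -0.0442 after scaling to total recovered reads.

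**Figure D2:**
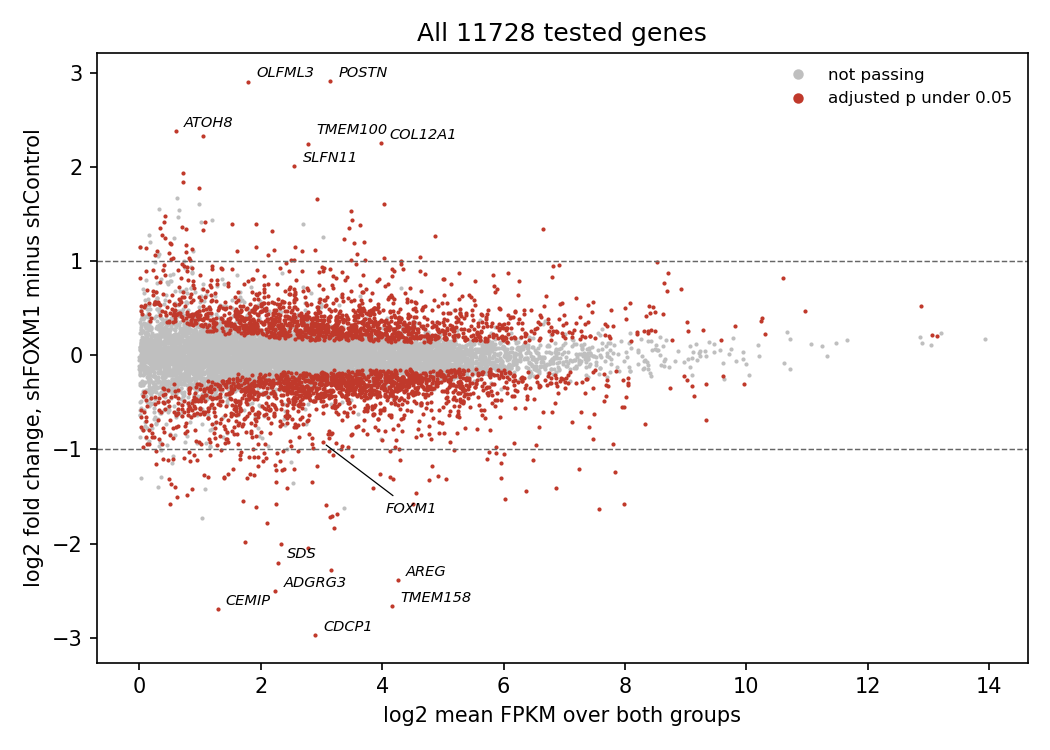
The log2 fold change of each of the 11728 tested genes (shFOXM1 minus shControl, vertical axis) against the log2 of its mean FPKM (horizontal axis). Red points passed the test, grey points did not, and dashed lines mark 2-fold changes; called changes reach 2.92 upward in POSTN and -2.97 downward in CDCP1.

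Mitosis and G2/M genes that FOXM1 is known to bind did not pass the test as a list. Of 56 tested members, 11 rose, 5 fell and 40 did not pass (13 and 6 adjusted over the list alone), with a median log2 fold change of 0.05 and a camera adjusted p of 0.132. AURKB, the kinase of the chromosomal passenger complex, fell from 20.1 ± 2.52 to 15.4 ± 1.04 FPKM (log2 fold change -0.37), and CCNB1, NEK2, TROAP and CKS1B, named after their values were seen, also fell. ASPM, a spindle pole protein gene, rose from 6.26 to 8.08 FPKM (log2 0.35). ANLN, which encodes the cytokinesis protein anillin, rose from 13.03 to 16.5 FPKM (0.33), and SKP2, a ubiquitin ligase subunit gene, from 18.6 to 23.2 FPKM (0.31). AURKB lost its call without shControl replicate 2 or shFOXM1 replicate 2 or 3 (adjusted p up to 0.0819), and ASPM without shFOXM1 replicate 1, 2 or 3 (up to 0.101). The list itself passed without shControl replicate 1 (median 0.08, adjusted p = 0.0460) or shFOXM1 replicate 2 (0.08, adjusted p = 0.0476), in the direction of higher values. Over all alternatives its adjusted p ran from 0.0460 to 0.705.

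Among 44 tested genes of G1/S and DNA replication, 11 rose, 4 fell and 29 did not pass (13 and 4 adjusted over the list alone), with a median of 0.07 and an adjusted p of 0.0531. CDC6, which loads the replicative helicase, rose from 13.6 ± 0.714 to 21.1 ± 0.994 FPKM (log2 fold change 0.62, SE 0.06, adjusted p = 5.05e-04). Its partner CDT1 rose from 14.6 to 18.6 FPKM, ORC1 from 6.55 to 8.31 FPKM and E2F8 from 1.23 to 1.84 FPKM. RFC2, CCNE1, POLA1 and MCM7, named after their values were seen, fell. CDT1 lost its call in 5 of 6 fits without 1 library, all but that without shControl replicate 1 (adjusted p up to 0.135), and E2F8 in all but that without shControl replicate 2 (up to 0.140). The list passed without shControl replicate 1 (median 0.13, adjusted p = 0.00495) or shFOXM1 replicate 2 (0.09, adjusted p = 0.0445), with a range of 0.00495 to 0.669 over all alternatives.

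Genes of DNA repair and the DNA damage response rose slightly as a list. Of 40 tested, 9 rose, 1 fell and 30 did not pass, with the same counts adjusted over the list alone, a median of 0.08 and an adjusted p of 0.0195. The adjusted p was 0.484 with an estimated correlation. The damage kinase gene ATM rose from 1.96 to 2.92 FPKM (log2 0.48) and the nuclease gene MRE11 from 3.43 to 4.98 FPKM (0.48). XRCC3, a homologous recombination gene with 76.7% of its exonic bases shared with other genes, fell from 4.28 to 3.11 FPKM (log2 -0.41). Without shFOXM1 replicate 3 the list no longer passed (median 0.05, adjusted p = 0.0689; range 0.00425 to 0.484 over all alternatives). Without single libraries ATM lost its call for shFOXM1 replicate 1 or 3 (adjusted p up to 0.0746), and XRCC3 for shControl replicate 1 or 2 or shFOXM1 replicate 2 or 3 (up to 0.112).

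Among factors that define SCLC subtypes, NEUROD1, ATOH1 and POU2F3 were near or at 0. NEUROD1 and ATOH1 had 0 reads in every sample, which allows up to 0.0605 and 0.0906 FPKM. POU2F3 had at most 2 reads per sample. YAP1, a Hippo pathway coactivator, was at 15.7 ± 1.21 FPKM in shControl and 18.2 ± 0.122 FPKM in shFOXM1 samples (log2 fold change 0.21, SE 0.06, adjusted p = 0.0404), a call lost without shControl replicate 2 or shFOXM1 replicate 1, 2 or 3 (adjusted p up to 0.112). Of 34 neuroendocrine genes only 9 reached the filter, of which 2 rose, 3 fell and 4 did not pass (2 and 4 adjusted over the list alone), with a median of -0.17 and an adjusted p of 0.279. SNAP25, a synaptic fusion protein gene, fell from 2.63 to 1.17 FPKM (log2 -0.91), the Notch pathway gene HES6 from 3.27 to 1.76 FPKM (-0.72) and SYN1 from 6.72 to 5.14 FPKM (-0.35), whereas RTN1 rose from 21.2 to 30.7 FPKM (0.52), as did PCSK1, named after its values were seen. SYN1 kept its call only without shControl replicate 2 (adjusted p up to 0.0696 in the other fits without 1 library).

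Non-neuroendocrine, YAP and Notch genes rose as a list. Of 25 tested, 11 rose, 1 fell and 13 did not pass (11 and 2 adjusted over the list alone), with a median of 0.15 and an adjusted p of 0.00297. The adjusted p was 0.221 with an estimated correlation. The YAP target CTGF rose from 3.56 ± 0.464 to 7.69 ± 0.555 FPKM (log2 1.02), the caveolar coat gene CAV1 from 8.57 to 17.6 FPKM (1.01) and the receptor NOTCH3 from 47.6 ± 2.39 to 87.7 ± 1.71 FPKM (0.88). EPHA2, a receptor tyrosine kinase gene, fell from 6.82 to 3.95 FPKM (-0.72). Of 12 tested mesenchymal genes, 6 rose, 2 fell and 4 did not pass (7 and 4 adjusted over the list alone; median 0.23, adjusted p = 0.145). FN1, fibronectin, rose from 294 ± 21.9 to 539 ± 8.49 FPKM and SNAI2, an epithelial-mesenchymal transition factor, fell from 6.64 to 2.93 FPKM. Of 20 epithelial genes 6 were tested, of which JUP rose from 2.15 to 5.39 FPKM, CLDN7 fell from 3.87 to 2.74 FPKM, KRT7, named after its values were seen, fell and 3 did not pass (1 higher and 2 lower adjusted over the list alone; median 0.04, adjusted p = 0.675). CLDN7 lost its call without shControl replicate 1 or 2 or shFOXM1 replicate 1 or 3 (adjusted p up to 0.100).

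Markers of other cell types were mostly near 0. Of 10 fibroblast markers 3 were tested, of which LUM rose from 0.971 ± 0.227 to 3.18 ± 0.285 FPKM and COL3A1 from 33.8 ± 1.51 to 52.7 ± 0.390 FPKM, while ACTA2 did not pass (2 higher adjusted over the list alone; median 0.64, adjusted p = 0.0531). In the same samples COL1A1 was at 0.143 and 0.0974 FPKM and COL1A2 at 0.00200 and 0.0916 FPKM in shControl and shFOXM1. The list passed without shControl replicate 1 (adjusted p = 0.0308) or shFOXM1 replicate 1 (0.0365) or 2 (0.0476). It passed in 10 of 24 alternatives, fry included, among them TPM (0.0289), voom (0.0265) and scaling to total recovered reads (0.0326), with a range of 0.0265 to 0.484 over the camera alternatives. Of 10 leukocyte, 7 endothelial and 10 hepatocyte markers, 1, 0 and 1 reached the filter. The first was CD14 (4.45 and 3.25 FPKM) and the last FGB, a fibrinogen chain gene (201 and 182 FPKM). Neither passed over all genes. Adjusting over a list with 1 tested gene changes nothing, so both were lower only at an unadjusted limma p under 0.05. Of the 11728 tested genes, 4759 had such a p.

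The unfolded protein response list had the largest median change. Of 18 tested members, 16 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone, a median of 0.76 and an adjusted p of 1.52e-11. The adjusted p was 0.464 with an estimated correlation. HERPUD1, a component of endoplasmic reticulum-associated degradation, rose from 57.0 ± 7.09 to 145 ± 5.67 FPKM (log2 fold change 1.34, SE 0.09, adjusted p = 1.07e-04), and the co-chaperone DNAJC3 from 15.8 to 33.4 FPKM (1.05). PPP1R15A, which encodes a phosphatase subunit that restores translation, fell and XBP1 did not pass, both named after their values were seen. Of 12 heat shock genes, 3 rose and 9 did not pass (2 higher adjusted over the list alone; median 0.07, adjusted p = 0.0909). HSPA8, a constitutive chaperone, rose from 82.2 ± 1.24 to 160 ± 8.09 FPKM (log2 0.95) and its cofactor BAG3 from 22.0 to 29.3 FPKM (0.41). The heat shock list passed without shControl replicate 1 (adjusted p = 0.0425) or shFOXM1 replicate 2 (0.0374), with a range of 0.0374 to 0.646 over the camera alternatives. Of 21 ATF4 targets, 1 rose, 6 fell and 14 did not pass (1 and 7 adjusted over the list alone); the median was 0.05, the mean -0.06 and the test pointed down (adjusted p = 0.864). NUPR1 fell from 1.79 to 0.844 FPKM and PCK2, mitochondrial phosphoenolpyruvate carboxykinase, from 22.2 to 17.5 FPKM, a call lost without shControl replicate 2 (adjusted p = 0.0544).

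Immediate early genes, which growth factors and stress induce within minutes, fell together, and their list had been fixed as a sign of handling. Of 13 tested, 11 fell and 2 did not pass (12 adjusted over the list alone), with a median of -0.58 and an adjusted p of 5.55e-07. The adjusted p was 0.221 with an estimated correlation. EGR1 fell from 79.2 ± 5.62 to 38.3 ± 1.05 FPKM (log2 fold change -1.04, SE 0.06) and NR4A1 from 5.74 to 2.52 FPKM (-1.04). Of 17 genes of NF-kB and secretory inflammation, 12 fell and 5 did not pass (13 lower and 2 higher adjusted over the list alone), with a median of -0.43 and an adjusted p of 6.33e-06. The adjusted p was 0.464 with an estimated correlation. IL1B fell from 14.7 ± 0.845 to 3.77 ± 0.294 FPKM (-1.84) and IL6 from 120 ± 13.5 to 44.1 ± 5.28 FPKM (-1.44). Of 19 interferon response genes, 2 rose, 6 fell and 11 did not pass (3 and 6 adjusted over the list alone; median -0.01, adjusted p = 0.519), among them OASL, from 3.48 to 1.81 FPKM, and IFIT2, from 4.57 to 2.59 FPKM, which both fell. Of 13 genes of MHC class I antigen presentation, ERAP1 rose from 11.96 to 16.8 FPKM and HLA-B, whose reads may be split with related HLA genes, from 6.64 to 8.44 FPKM, TAP1, named after its values were seen, fell and 10 did not pass, with the same counts adjusted over the list alone (median 0.0056, adjusted p = 0.593).

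**Figure D3:**
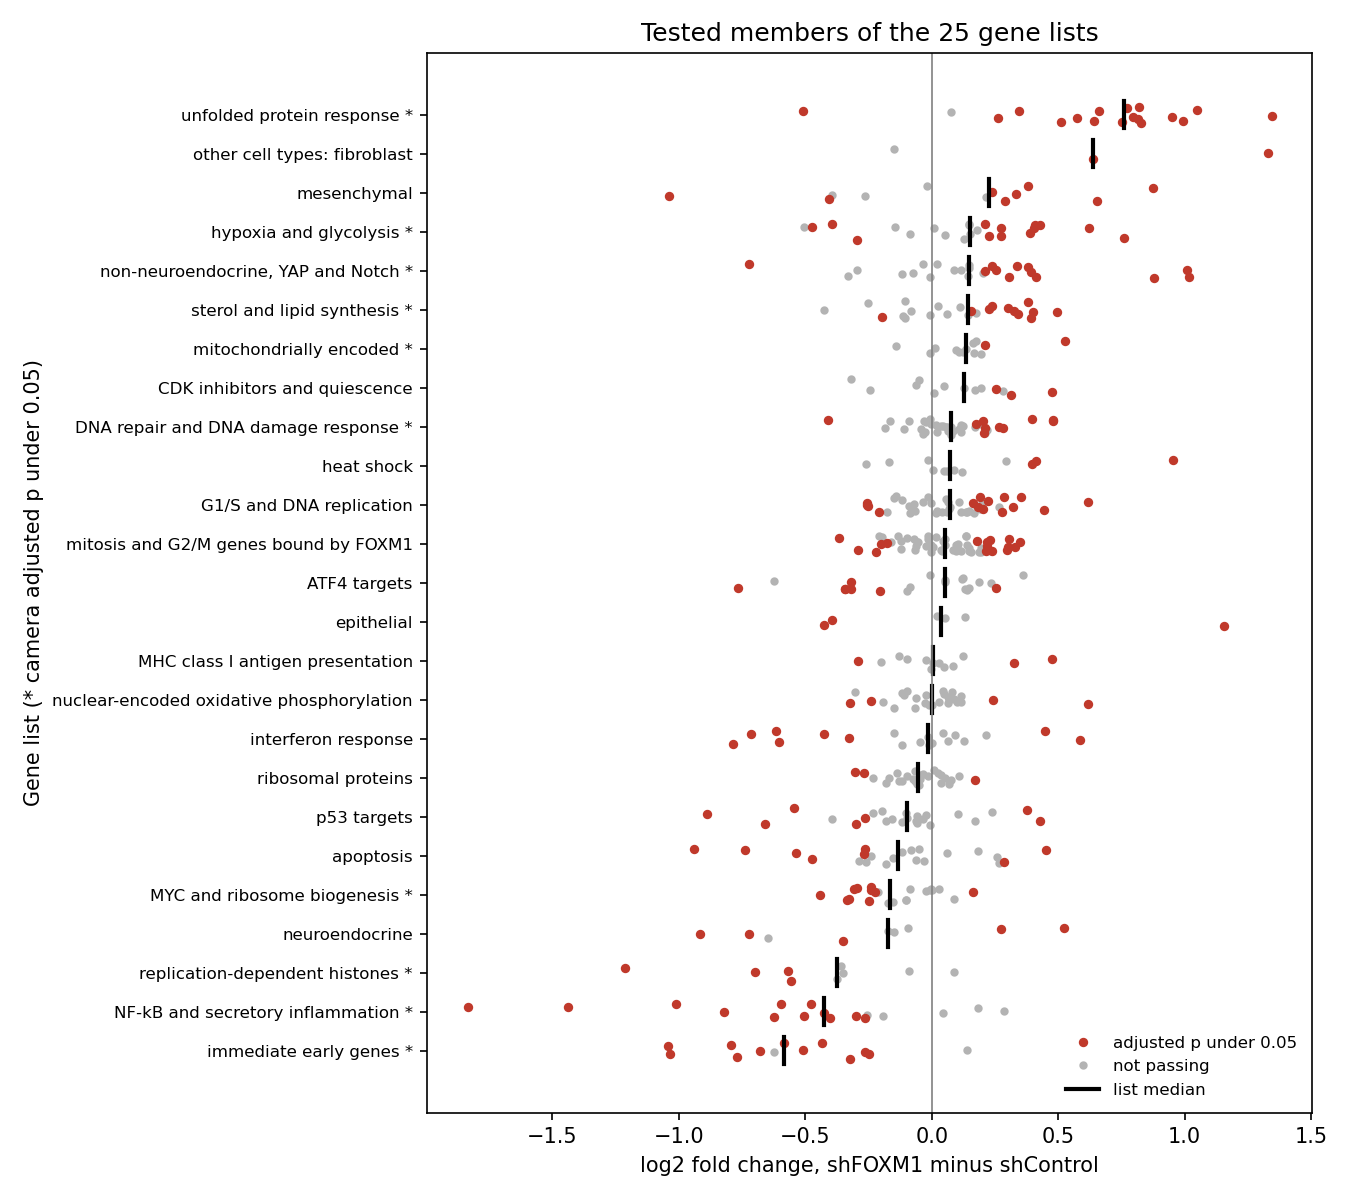
The log2 fold change (shFOXM1 minus shControl, horizontal axis) of each tested member of the 25 lists tested, ordered by list median (black bars). Red points passed over all genes, grey points did not, and asterisks mark lists with a camera adjusted p under 0.05 at the preset correlation; medians run from -0.58 for immediate early genes to 0.76 for the unfolded protein response.

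Of 25 tested p53 targets, 2 rose, 5 fell and 18 did not pass (2 and 7 adjusted over the list alone), with a median of -0.10 and an adjusted p of 0.0997. GDF15, a stress-induced cytokine, fell from 230 ± 30.1 to 124 ± 16.0 FPKM (log2 -0.89), GADD45A from 47.6 ± 11.4 to 29.4 ± 1.70 FPKM (-0.66) and PHLDA3, an inhibitor of AKT, from 11.1 to 7.46 FPKM (-0.54), as did BAX and AEN, named after their values were seen. CCNG1 rose from 82.7 to 111 FPKM (0.43), as did ZMAT3, also named after its values were seen. GADD45A lost its call without shFOXM1 replicate 3 (adjusted p = 0.0537), and the list passed without shControl replicate 1 (median -0.10, adjusted p = 0.0456; range 0.0435 to 0.667 over all alternatives). Of 22 apoptosis genes, 2 rose, 6 fell and 14 did not pass (2 and 8 adjusted over the list alone; median -0.14, adjusted p = 0.0740), and the list passed without shFOXM1 replicate 1 (adjusted p = 0.0436; range 0.0436 to 0.616 over the camera alternatives). The survival factor MCL1 fell from 294 ± 23.4 to 153 ± 6.31 FPKM (log2 -0.94) and the initiator caspase CASP9 from 4.83 to 2.70 FPKM (-0.74). Of 13 CDK inhibitors and quiescence genes, 3 rose and 10 did not pass, with the same count adjusted over the list alone (median 0.13, adjusted p = 0.1197); RBL2, a pocket protein, rose from 7.70 to 10.9 FPKM and GAS1, named after its values were seen, also rose.

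Hypoxia and glycolysis genes rose (10 up, 3 down and 10 not passing of 23, with 10 and 3 adjusted over the list alone; median 0.15, adjusted p = 0.0195), led by the glycolytic regulator PFKFB4, from 1.67 to 3.15 FPKM (adjusted p = 0.0548 with no filter; range 1.74e-04 to 0.0548), and the mitophagy receptor BNIP3L, from 13.9 to 21.7 FPKM. The hypoxia list had an adjusted p of 0.616 with an estimated correlation and 0.0606 by fry. It did not pass without shControl replicate 3 (0.0554) or shFOXM1 replicate 2 (0.0525), with a range of 0.00124 to 0.616 over all alternatives. Sterol and lipid synthesis genes rose (10 up, 1 down and 12 not passing of 23, with 11 and 3 adjusted over the list alone; median 0.14, adjusted p = 0.0195), with STARD4, a sterol carrier, from 16.3 to 23.1 FPKM and HMGCS1, a mevalonate pathway enzyme, from 10.0 to 13.4 FPKM. The sterol list had an adjusted p of 0.484 with an estimated correlation and did not pass without shControl replicate 3 (0.0666; range 0.00410 to 0.484 over all alternatives). Of 27 nuclear-encoded oxidative phosphorylation genes, 2 rose, 2 fell and 23 did not pass (2 and 0 adjusted over the list alone; median 0.0018, adjusted p = 0.735). Among them COX7B rose from 34.7 to 53.5 FPKM and COX6A1 fell from 47.8 to 38.0 FPKM, the latter losing its call without shFOXM1 replicate 2 or 3 (adjusted p up to 0.108).

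The mitochondrial chromosome took 7.35% to 7.68% of reads in shControl and 8.16% to 8.34% in shFOXM1 samples. Mitochondrially encoded genes rose as a list (median 0.13, adjusted p = 0.0170), but their median was -0.01 after quantile normalization. The adjusted p was 0.484 with an estimated correlation, 0.384 with no filter and 0.0524 without shControl replicate 3, with a range of 5.43e-04 to 0.484 over all alternatives. Of 13 tested, 2 rose and 11 did not pass (1 higher adjusted over the list alone). MT-ND4L, a complex I subunit gene, rose from 6175 to 8883 FPKM (log2 0.53), by 0.26 after quantile normalization, and lost its call with no filter (adjusted p = 0.433; range 3.88e-06 to 0.433). MT-CO2, a cytochrome oxidase subunit gene, rose from 8423 to 9726 FPKM, but its log2 fold change was -0.03 after quantile normalization. Among fits without 1 library it kept its call only without shControl replicate 1 (adjusted p up to 0.150 in the others; range 0.00376 to 0.779 over all alternatives).

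MYC and ribosome biogenesis genes fell as a list (1 up, 9 down and 12 not passing of 22, with 1 and 11 adjusted over the list alone; median -0.16, adjusted p = 0.0123); the adjusted p was 0.616 with an estimated correlation. RRP12 fell from 30.2 to 22.1 FPKM and NOP16 from 28.5 to 22.5 FPKM, both ribosome assembly factors. Replication-dependent histones fell (4 of 9 down and 5 not passing, with 4 adjusted over the list alone; median -0.38, adjusted p = 0.0123), with an adjusted p of 0.484 with an estimated correlation. Without shControl replicate 3 the median was -0.13 (adjusted p = 0.0436; range 6.89e-04 to 0.484). HIST1H2AC fell from 8.33 ± 0.851 to 3.30 ± 0.0947 FPKM and HIST1H1C from 30.3 to 18.4 FPKM. Transcripts of this list mostly lack a poly(A) tail, so it is also a sign of how RNA was selected, which was not tested. Of 28 ribosomal protein genes, 1 rose, 2 fell and 25 did not pass (0 and 0 adjusted over the list alone; median -0.05, adjusted p = 0.310). RPL8 fell from 717 to 580 FPKM and RPLP1 from 571 to 474 FPKM, calls that were lost without shFOXM1 replicate 1, 2 or 3 (adjusted p up to 0.0944 and 0.0945), and RPL15, named after its values were seen, rose.

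In all, 10 of the 25 lists passed in camera at the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.221 and 2 lists had an unadjusted p under 0.05. By fry, which does not compare a list with other genes, 16 lists passed.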

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

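The tests with reads scaled to total recovered reads, with or without mitochondrial genes, were chosen only after the data were seen; the other alternatives were planned.

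FOXM1 kept its direction and call in all 23 alternatives run, with log2 fold changes from -1.02 to -0.80. Of 92 gene counts under alternatives, 83 stayed within 1.5 times the reported count and 9 were lower by more. Of 624 list results, 557 kept direction and side of the threshold, 18 lost a call, 31 gained one and 18 changed direction. Of 1726 values of named genes, 1631 kept both, 94 lost a call and 1 changed direction. The named genes tested were all called in the reported fit, most of them picked for it, so they could not gain a call. Of the 3199 calls over all genes, 2039, 1987 and 1900 were kept without shFOXM1 replicate 1, 2 or 3. Without shControl replicate 1, 2 or 3, 2694, 2354 and 2428 were kept.

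Without 1 library the genes called higher ranged from 925 to 1562 and those called lower from 1017 to 1555, with fewer samples in each fit. Testing all genes with no filter gave 1114 lower genes. The genes at least 2-fold higher were 39 with a pseudocount of 1 and 26 at a mean FPKM of at least 5, where 49 were at least 2-fold lower. The replicate block called 1214 genes higher and 1475 lower, and kept 2532 of the 3199 calls. Deviations from the group means correlated across genes at 0.0225, 0.0468 and 0.0710 for like-numbered samples. For unlike-numbered samples they correlated at -0.0917 to 0.0443. With 3 samples per group the deviations are tied to each other, so these values cannot settle whether the numbers pair the samples.

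List medians below are log2, and the cause of each change was not tested. Without 1 library the median ranged from 0.0269 to 0.0801 for mitosis and G2/M, 0.0588 to 0.127 for G1/S, 0.0465 to 0.103 for DNA repair and -0.120 to -0.0601 for p53 targets. It ranged from -0.0813 to 0.00984 for interferon response, -0.0111 to 0.0589 for MHC class I, -0.0295 to 0.0762 for ATF4 targets, -0.0914 to 0.0175 for ribosomal proteins and -0.00574 to 0.0609 for epithelial genes. For histones it ranged from -0.561 to -0.128, for heat shock 0.0380 to 0.116, for neuroendocrine genes -0.273 to -0.120, for apoptosis -0.166 to -0.0853 and for oxidative phosphorylation 3.98e-04 to 0.0506. The G1/S list gained a call with no filter (0.0734), at a mean FPKM of at least 0.1 (0.0734), with quantile normalization (0.115) and with sample quality weights (0.116). At a mean FPKM of at least 5, DNA repair lost its call (0.0551) and p53 targets (-0.109) and mesenchymal genes (0.240) gained one; ribosomal proteins gained one with quantile normalization (-0.0855). With an estimated correlation all 10 called lists lost their calls, DNA repair (0.0755) and the non-neuroendocrine list (0.149) among them.

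Directions reversed with no filter for neuroendocrine (0.0105) and epithelial genes (-0.0255), and at a mean FPKM of at least 0.1 for interferon response (0.0225) and epithelial genes (-0.101). Rescaling to TPM reversed MHC class I (-0.0396), oxidative phosphorylation (-0.0470) and epithelial genes (-0.0104). Total recovered reads reversed MHC class I (-0.0262) and oxidative phosphorylation (-0.0345), as did reads outside mitochondria (-0.0159 and -0.0227). Quantile normalization reversed the mitochondrially encoded list (-0.0111) and MT-CO2 (-0.0311).

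The order of the largest changes depended on the pseudocount and on voom, under which ATOH8 reached 4.24. Over all alternatives the adjusted p ran from 0.00332 to 0.0849 for AURKB, 0.00194 to 0.102 for ASPM, 0.00213 to 0.144 for CDT1, 0.0124 to 0.141 for E2F8 and 1.77e-04 to 0.0746 for ATM. It ran from 0.00248 to 0.118 for XRCC3, 0.0131 to 0.139 for YAP1, 0.00596 to 0.0733 for SYN1, 0.00886 to 0.107 for CLDN7 and 2.48e-04 to 0.0667 for GADD45A. For PCK2 it ran from 0.00125 to 0.0607, for COX6A1 from 0.00534 to 0.110, for RPL8 from 0.00174 to 0.136 and for RPLP1 from 0.00203 to 0.129. With no filter MT-ND4L (0.433) and PFKFB4 (0.0548) lost their calls.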

Other observations

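The 3 patterns below were picked from these data, and the tests of scaling and of the matrix genes near 0 in shControl samples were chosen only after the result was seen.

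FOXM1 fell by 0.93 on the log2 scale while the median of its mitosis and G2/M list was 0.05. The 9 differences between an shFOXM1 and an shControl sample in the mean log2 value of that list ran from -0.0285 to 0.125. Of the 9, 8 were above 0, but they pair only 6 samples and are not independent. The difference between the group means was 0.0490 (SE 0.0316). On the deposited scale this argues against a fall hidden by the spread between samples. The list median was 0.00573 after rescaling to TPM and 0.0171 after scaling to total recovered reads. Under the 6 scalings the list median exceeded the median of all tested genes by at least 0.0613. A factor per library moves all genes alike, so scaling could hide only a fall shared by all genes, and without spike-in rows that cannot be told apart from no fall. That 48 h of induction or the remaining FOXM1 transcript leaves these genes at their level stays open and untested here.

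The unfolded protein response list rose while the immediate early and NF-kB lists fell. These calls were lost with an estimated correlation (adjusted p 0.464, 0.221 and 0.464). After a smooth trend of log2 fold change on gene length, GC content and expression level was removed from all tested genes, the 3 list medians kept at least 71.7% of their size, and without any 1 library they kept at least 84.7%, which argues against these as the whole cause. Lower ERK output was a candidate explanation for the immediate early part. A list of 10 ERK output genes, 2 of which (EPHA2 and CCND1) had been seen in another list, had a median of 0.0880. Of 9 tested members, 2 were higher (DUSP6 and ETV5) and 3 lower (PHLDA1, DUSP4 and EPHA2). As written before it was run, the test counted a median that was not negative against lower ERK output, and it came out so. The SD of the members' log2 fold changes was 0.551, which measures the spread between genes and not the error of the median. Camera at the preset correlation gave an unadjusted p of 0.999. As a set these genes gave no sign of lower ERK output. Members changed both ways, so lower ERK output is not excluded and stays open. An effect of the hairpin other than loss of FOXM1 is confounded with the groups, as is any difference in handling between them.

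POSTN, COL12A1, FN1, COL3A1 and LUM rose together with ATOH8, TMEM100 and NOG, a BMP antagonist gene that rose from 0.490 to 2.03 FPKM. RNA from fibroblasts could bring such matrix transcripts. The test written before it was run asked whether COL1A1, COL1A2 or COL3A1, all members of the fixed fibroblast list, rose by more FPKM than POSTN (14.3). COL3A1 did, by 19.0, which goes with fibroblasts. COL3A1 was however already at 33.8 FPKM in shControl samples, and the highest rise among COL1A1, COL1A2, DCN and SPARC, which were near 0 there and are abundant in fibroblasts, was 0.0896 FPKM, far below what the rise of POSTN would need. For higher BMP and SMAD signalling, 8 target genes had a median of -0.0116 with 1 of 7 tested members higher (ID4) and none lower. As written before it was run, this test counted a median that was not positive against such signalling, and it came out so. The SD of the members' log2 fold changes was 0.314, which measures the spread between genes and not the error of the median. Camera at the preset correlation gave an unadjusted p of 0.576. As a set these genes gave no sign of higher BMP and SMAD signalling. With 7 tested genes a small rise is not excluded, so such signalling stays open.

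With 6 samples there are 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1498 genes higher and 1701 lower, and 61 and 100 by at least 2-fold; in each case 1 split, the real one, gave as many. Since a split and its mirror count as 1, which swaps higher and lower, the highest other split gave 1 for each count, from a single gene. For gene lists the real split called 10, the highest other called 13, and 3 of the 10 splits gave as many. Each other split mixes the groups, which leaves the group difference in the residual and part of it in the contrast, so gene and list counts are not compared with each other here.

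Genes that share exonic bases with other genes can be listed far too low where reads that overlap several genes are left out. Of 644 list members and named genes, 12 share over 50% of their exonic bases, among them PRC1 (58.4%, mean 0.368 FPKM), whose value is not read as absence here.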
